A study of Mus musculus with 4 samples.

How the data were processed

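Single-cell RNA sequencing (10x Chromium 3' libraries, version 3.1 chemistry) was done on isolated pancreatic islets of 4 mice, 2 with and 2 without the microRNA gene Mir216a. The deposited matrices hold counts: unique molecular identifiers (UMIs) per gene and barcode, not normalised, for 31253 genes, made with Cell Ranger 4.0.0 per the file headers. The submitters' notes also name Cell Ranger 3.1.0, cutadapt 2.10 and Seurat, and the builds mm10 and GRCm38; which role each had is not given in the sources used here. A further table by the authors holds the natural log of 1 plus counts per 10000, although it is named as scaled; its values are not centred, and it holds 15034 barcodes, all with over 200 detected genes and under 5% mitochondrial UMIs when checked against the raw matrices. Deposited feature and barcode lists, classed as other, give gene identifiers, symbols and barcodes in matrix order. The annotation used was GENCODE vM21 on GRCm38, the build the authors name.

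Groups followed the genotype labels, the mouse was the replicate, and no label pairs mutant with wild-type mice. The comparisons, tests, gene lists, cell type markers, rule for named genes and most alternatives were chosen before the data were examined. A barcode was kept with at least 500 detected genes, at least 1000 UMIs and at most 20% mitochondrial UMIs. Scrublet as run in scanpy on each mouse alone called 14 of 13762 passing barcodes (0.102%). That is under the 0.5% taken as the mark of a working call, so doublets remain among the 13748 kept cells. Cells were normalised to 10000 UMIs, and 2000 variable genes, 30 principal components and 15 neighbours fed Leiden clustering at resolution 1.0 without integration. A cluster took the name of the type with the highest score. The score was the median over the type's fixed markers of the cluster's level divided by the highest level of any cluster. A cluster stayed unnamed when fewer than 3 of these markers were found in at least 5% of its cells. So it did when markers of another type led its 10 top genes, or when its UMIs were few and no own marker led. This naming rule was rewritten after the clusters were seen, while the markers stayed fixed. It left 7 of 24 clusters unnamed, holding 23.2% and 16.9% of the cells of the mutant mice and 16.6% and 11.9% of those of the wild-type mice. Classes are called beta-like, alpha-like and so on, because their names rest on transcripts.

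UMIs were summed per mouse and class. Each class with at least 20 cells in every mouse was tested alone with edgeR 4.0.16 (quasi-likelihood F test, two-sided, TMM, filterByExpr, genotype as the one term). P values were adjusted by Benjamini-Hochberg within the class at 0.05. The acinar-like class has under 20 cells in every mouse and was fitted all the same, since the series title names exocrine function; that was decided after the cell numbers were seen. Fold changes are mutant over wild type on the log2 scale with their standard error (SE), and levels are counts per 1000000 (CPM). Of the 33 fixed lists, those with at least 5 tested genes were tested with camera (limma 3.58.1, correlation 0.01), with an estimated correlation and with fry. With 2 mice per group the estimated correlation leaves few residual degrees of freedom, and its power was not simulated. How often a truly shifted list would pass there is not known, so a list that does not pass says little. At the preset correlation of 0.01 camera treats the genes of a list as nearly independent. Its p values are too small where such genes move together. Differences in effect between classes were tested as the interaction of class and genotype with the mouse as a block. Shares of cells were compared with two-sided exact permutation tests. With 2 against 2 mice there are 6 arrangements, so p cannot go below 0.33. Cycling cells carried a UMI of at least 2 of 7 cell cycle markers after thinning every cell to 10000 UMIs, and cells with fewer UMIs were left out. For sites of the miR-216a-5p seed, the longest annotated 3' untranslated region of 21037 genes was searched and set against other 7-base sequences matched within 20% on their number of genes. The plan was 1000 such sequences and 656 to 921 met the criteria, all of which were used.

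The genes named are, in beta-, alpha-, delta- and acinar-like cells, up to 12 per direction with the largest change among those passing with a mean of at least 20 CPM and groups that do not overlap, filled to 5 by the smallest p. Other classes took 3 per direction. Up to 4 passing members of each list were added, with a fixed set in every class: literature targets such as Smad7, Ybx1, Becn1 and Jak2, the islet hormones, Mki67, Nnt, sex-linked genes and genes within 2 Mb of Mir216a. Genes named by neither part are said to be chosen after their values were seen.

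On simulated counts with the same depths and 2 mice per group, edgeR found 84% of genes changed by 1 log2 unit in beta-like cells, 72% in alpha-like, 76% in delta-like, 45% in endothelial-like, 37% in macrophage-like and 10% in acinar-like cells. With nothing changed it called at most 3 genes in any class. Among calls of the simulated alpha against beta interaction 10.3% were false, on the 11468 genes tested in both classes rather than the 14757 of the interaction reported. A planted shift of 0.1 in genes with a seed site was found as 0.105.

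Alternatives were DESeq2 1.42.0, its size factors, no filter on low counts, thinning to the smallest sum, leaving out each mouse in turn, kept doublets, stricter cell filters, other Leiden resolutions, and leaving out markers of other classes or sex-linked genes. Chosen after the data were seen were the authors' barcodes, a ceiling of 2 times the class median of UMIs, leaving out clusters of which 1 mouse holds over 50%, leaving out beta-like cells with over 0.5% Gcg, counting unnamed clusters as beta-like, and leaving out each mouse in the interaction, cycling and seed tests. Leaving out a mouse assumes that the lone mouse varies like the other group. Exact binomial (Clopper-Pearson) 95% intervals and limits for a count of 0 (3 counts) cover counting error only. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scipy 1.17.1 and R 4.3.3 were used. The authors' table was not used here beyond its list of barcodes, and ductal-, Schwann- and T-like cells were too few for a test.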

Results

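The series profiled islets from 17-week-old male C57BL/6J mice that had eaten a 60% fat diet for 9 weeks from the age of 8 weeks. It set 2 mice lacking miR-216a (miR216a-/-, KO) against 2 wild-type (WT) mice. The title places the microRNA in proliferation and in endocrine and exocrine cell function, and the comparison asks what its loss changes in islet cells. KO replicates 1 and 2 gave 135290972 and 196743376 UMIs, and WT replicates 1 and 2 gave 191415787 and 184813655. After filtering, 2196 and 4188 KO cells and 4107 and 3257 WT cells were kept, with median depths of 47532.5 and 39427.5 UMIs in KO and 34133 and 48227 UMIs in WT. The sex was read from the counts: the Y-linked Ddx3y stood at 52.1 to 58.3 CPM in the 4 mice and Xist, which is expressed from the inactive X chromosome, at 0.141 CPM or less. Nnt, a mitochondrial transhydrogenase gene that differs between C57BL/6 substrains, lay at 2.13 to 2.41 CPM in all 4 mice.

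Islets of both genotypes were made up mostly of beta-like cells, and the share of cells so named was lower in both KO mice than in both WT mice. Beta-like cells were 55.3% ± 7.59 of kept cells in KO and 65.5% ± 4.0 in WT (SD, n = 2 mice per group). Glucagon-expressing alpha-like cells were 9.00% ± 1.05 in KO and 6.91% ± 0.390 in WT, and macrophage-like cells 3.03% ± 0.228 and 2.08% ± 0.255. Somatostatin-expressing delta-like cells were 6.15% ± 0.123 and 5.41% ± 0.345. For each of these 4 classes the KO and WT values did not overlap, which gives an exact permutation p of 0.33, the smallest that 2 against 2 mice allow. Endothelial-like cells overlapped at 5.33% ± 1.6 and 4.78% ± 0.468 (exact permutation p = 1). Among beta-, alpha- and delta-like cells alone, beta-like cells made up 78.3% ± 3.64 in KO and 84.2% ± 0.862 in WT. Cells in unnamed clusters were also more frequent in KO, at 20.1% ± 4.42 against 14.3% ± 3.26, but not with the strict cell filter (10.4% and 11%) or Leiden resolution 0.5 (7.24% and 8.46%), and the shares of the other classes move with them. An unnamed cluster of 407 low-UMI cells, mostly from KO mice, scores closest to beta cells; counted as beta-like it brings the difference from -10.3 to -4.10 percentage points, with overlapping groups (59.2% and 64.6% in KO, 63.3% and 68.7% in WT; exact permutation p = 0.667). With all 5 unnamed clusters closest to beta cells counted in, the difference is -4.64 points and the groups do not overlap (exact permutation p = 0.33). Leaving out KO replicate 1 brought the beta-like difference from -10.3 to -4.90 percentage points and the alpha-like one from 2.1 to 1.35. Without KO replicate 2 the beta-like difference was -15.6 points, and with the authors' barcodes the alpha-like one was 1.24 points. With those barcodes the groups overlapped in all 4 classes: beta-like cells were 67.2% and 61.1% in KO and 80.9% and 59.9% in WT (exact permutation p = 1), and p was 0.667 for alpha-, delta- and macrophage-like cells.

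**Figure D1:**
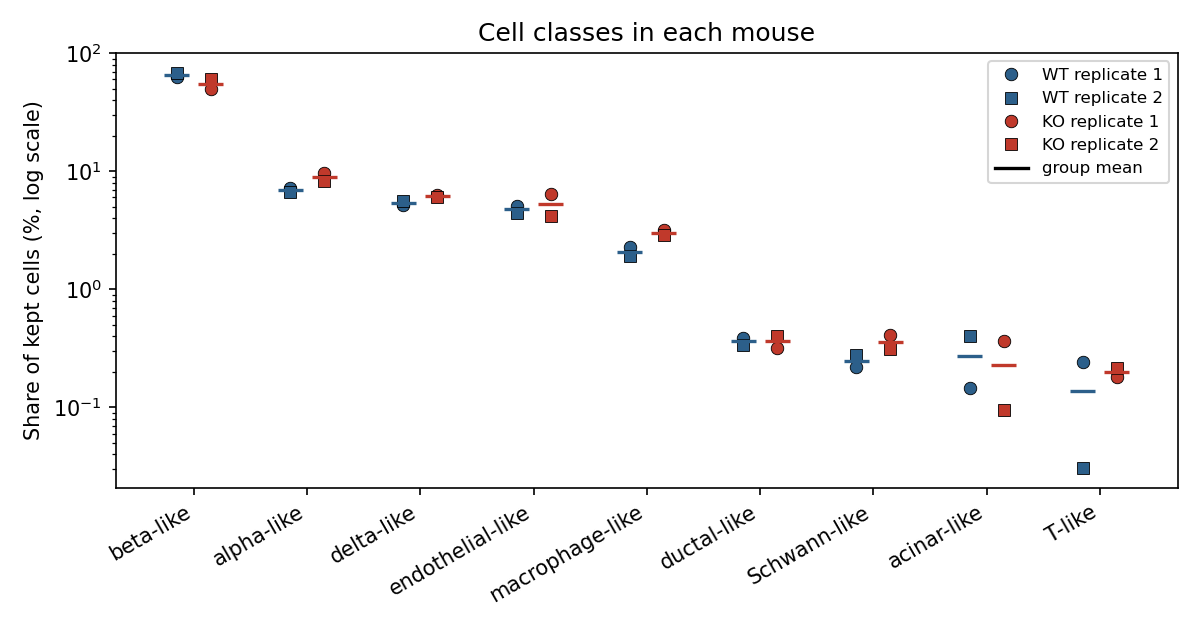
Share of kept cells in each class (percent, log scale) for the 4 mice, with WT in blue, KO in red, circles for replicate 1, squares for replicate 2 and bars for group means. Cells named beta-like lie lower in both KO mice, with means of 55.3% and 65.5%, though not once the unnamed low-UMI cluster is counted in, and alpha- and macrophage-like cells lie higher.

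In beta-like cells, transcripts of pancreatic digestive enzymes were higher in KO, and the transcript of the alpha cell hormone glucagon was lower. Sycn, which encodes the zymogen granule protein syncollin, rose by 1.19 (SE 0.10, adjusted p = 0.0250), from 7.72 ± 0.879 CPM in WT to 17.5 ± 1.54 CPM in KO (SD, n = 2). The trypsinogen gene Try4 rose by 1.82 (SE 0.16, adjusted p = 0.0250), from 6.53 ± 1.74 to 23 ± 2.36 CPM. Cpb1, Cel and Ctrl, which encode a carboxypeptidase, a lipase and a chymotrypsin-like protease, rose by 0.84, 1.04 and 1.22 (adjusted p = 0.0286 each). Gcg (ENSMUSG00000000394, GRCm38 chromosome 2, 62474530 to 62483650) fell by 0.78 (SE 0.08, adjusted p = 0.0286), from 925 ± 83.6 to 539 ± 21.9 CPM. The insulin genes Ins1 and Ins2 did not pass, at 0.17 (SE 0.10, adjusted p = 0.775) and 0.15 (SE 0.12, adjusted p = 0.810).

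Digestive enzymes as a list rose in beta-like cells: 25 of 26 tested members were higher in KO with a median of 0.92, 5 passed over all genes and 20 passed adjusted over the list alone. The camera adjusted p was 8.2e-102, and the adjusted p = 0.497 with an estimated correlation. Acinar injury and regenerating genes rose as well, 11 of 14 higher with a median of 0.31 (camera adjusted p = 0.000344), with none passing over all genes and 1 adjusted over the list alone; adjusted p = 0.599 with an estimated correlation. Digestive enzyme transcripts made up 0.0339% ± 0.000818 of beta-like UMIs in KO and 0.0186% ± 0.00294 in WT, against 74.8% and 72.1% in acinar-like cells. They were present in every class tested, at 14.1 to 20.9 UMIs per cell over the means of 5 classes, while total UMIs per cell differed 5.59-fold between those classes. The median beta-like cell held 12 and 9 Gcg UMIs in KO and 9 and 7 in WT (exact permutation p = 0.667), not corrected for total UMIs per cell. Beta-like cells in which Gcg took over 0.5% of UMIs were 0.547% and 0.748% of the class in KO and 4.19% and 1.03% in WT, and without them the Gcg change was 0.26 (adjusted p = 0.812; 6.2e-29 to 0.812 over all alternatives). It was -0.62 with the strict cell filter (adjusted p = 0.689), -0.79 with the authors' barcodes (0.141) and -1.06 with large barcodes left out (0.582).

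**Figure D2:**
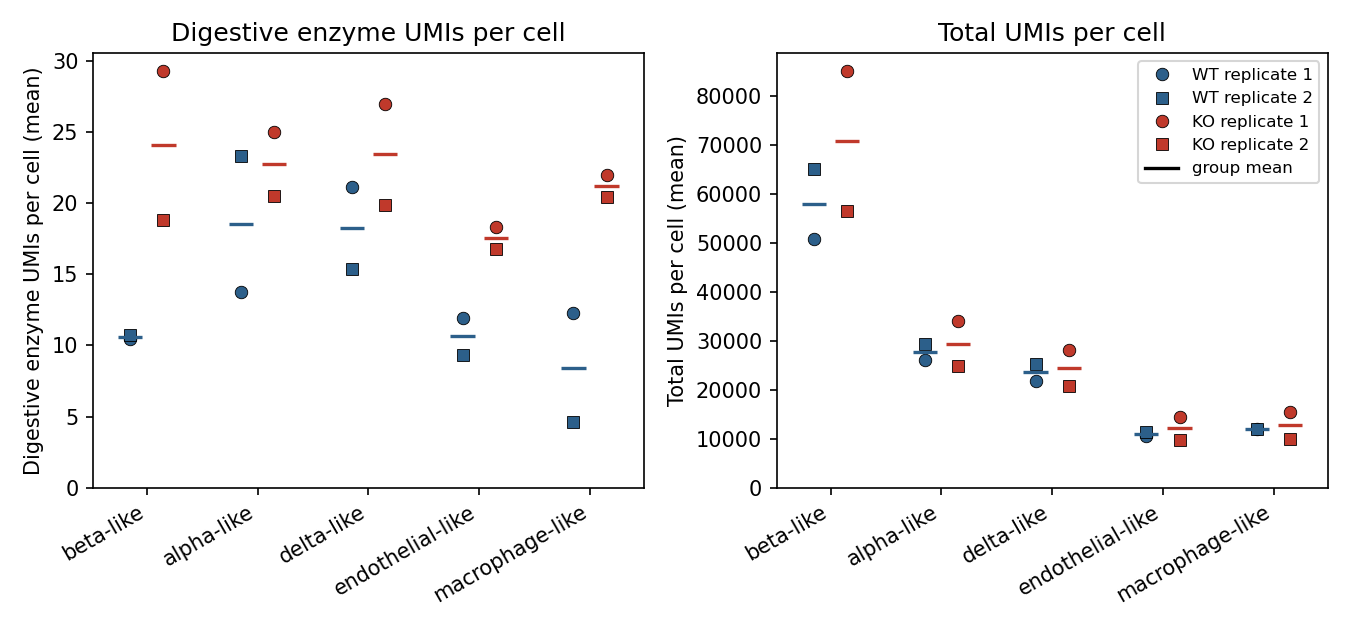
Mean UMIs per cell in 5 classes for digestive enzyme genes (left) and for all genes (right), with WT in blue, KO in red, circles for replicate 1, squares for replicate 2 and bars for group means. Beta-like cells held 24.1 enzyme UMIs per cell in KO and 10.6 in WT, macrophage-like cells 21.2 and 8.45, and endothelial-like cells 17.6 and 10.6. The groups overlap in alpha-like cells (25 and 20.5 in KO, 13.7 and 23.3 in WT) and in delta-like cells (27 and 19.9, 21.2 and 15.4), with an exact permutation p of 0.667 in each.

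Other lists moved by less in beta-like cells. Ribosomal protein genes rose, 75 of 80 higher with a median of 0.07 (camera adjusted p = 2.3e-06), and nuclear-encoded oxidative phosphorylation genes rose, 65 of 76 higher with a median of 0.05 (camera adjusted p = 0.000542). Mitochondrially encoded genes fell, 2 of 13 higher with a median of -0.21 (camera adjusted p = 2.7e-09). The median mitochondrial share of UMIs over all kept cells, a measure of cell quality, was lower in KO as well, at 3.53% and 3.69% against 4.44% and 4.71% in WT. The unfolded protein response, which serves protein folding in the endoplasmic reticulum, fell with a median of -0.11, 2 of 21 members higher (camera adjusted p = 0.000241). Alpha cell function genes fell, 3 of 14 higher with a median of -0.15 (camera adjusted p = 0.00024); Gcg passed over all genes and 1 gene passed adjusted over the list alone. With an estimated correlation the adjusted p of these 5 lists lay between 0.510 and 0.695. No member of the first 4 lists passed over all genes, and 5 mitochondrially encoded genes passed adjusted over the list alone. The unfolded protein response was lost without KO replicate 1 (adjusted p = 0.175) and without WT replicate 2 (0.350), and alpha cell function without KO replicate 2 (0.0789). Mitochondrially encoded genes were lost without KO replicate 1 (0.0978), ribosomal proteins without WT replicate 1 (0.0969) and oxidative phosphorylation without KO replicate 2 (0.0626). In all, camera called 13 of 33 lists in beta-like cells, and with an estimated correlation or by fry it was 0.

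The beta-like test covered 14829 genes on 93173045 to 144743881 UMIs per mouse. By edgeR 6 genes passed, 5 up and 1 down, and 1017 had an unadjusted p under 0.05. DESeq2 called 46, and the groups did not overlap in 37.9% of genes, against 33.3% by chance. The count was 118 without KO replicate 1, 115 without KO replicate 2 and 30 without WT replicate 1. It was 2 with the strict cell filter, 3 with large barcodes left out, 12 without the clusters mostly of 1 mouse and 302 with no filter on low counts. In edgeR it was 0 with markers and enzymes of other classes left out and 0 with the authors' barcodes, with 1006 and 780 genes at an unadjusted p under 0.05; DESeq2 was not run on these. Cpb1 and Cel did not pass without WT replicate 2 (adjusted p = 0.0528 and 0.0761). Over all alternatives the adjusted p of the 5 enzyme genes ranged from 1.2e-93 to 0.642. Among genes lower in KO with the smallest p, none passing apart from Gcg, Phactr3 stood at -0.57 (adjusted p = 0.123), the kinetochore motor gene Cenpe at -1.09 (0.126), the mitotic ubiquitin-conjugating enzyme gene Ube2c at -1.0 (0.198) and the hypoxia-inducible mitochondrial gene Higd1a at -1.42 (0.198). Without beta-like cells rich in Gcg, Higd1a stood at -0.27 (adjusted p = 0.917).

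Proliferation was read from beta-like cells, where transcripts of the G2 and M phases of the cell cycle were lower in KO. None of the 28 list members was higher in KO, with a median of -0.76, and the list fell by camera (adjusted p = 4.2e-32). With an estimated correlation the adjusted p = 0.577; none of the 28 genes passed over all genes and 15 passed adjusted over the list alone. Mki67, a marker of dividing cells, stood at -0.55 (SE 0.29, adjusted p = 0.766), with 4.46 and 2.02 CPM in KO and 4.55 and 4.72 CPM in WT, and Top2a at -0.57 (adjusted p = 0.766; chosen after its values were seen). S phase genes fell less, 3 of 26 higher with a median of -0.14 (camera adjusted p = 0.000542; adjusted p = 0.695 with an estimated correlation). This list was lost without KO replicate 2 (adjusted p = 0.800), and none of its genes passed over all genes or adjusted over the list alone. Cells with at least 2 of 7 cell cycle markers were 1.11% ± 0.542 of beta-like cells in KO and 1.95% ± 0.267 in WT at 10000 UMIs per cell (SD, n = 2), with an exact permutation p of 0.33. KO replicate 1 held 16 such cells of 1068 (1.5%, exact 95% interval 0.859 to 2.42%) and KO replicate 2 held 18 of 2462 (0.731%, 0.434 to 1.15%). WT replicate 1 held 38 of 2153 (1.76%, 1.25 to 2.41%) and WT replicate 2 held 42 of 1960 (2.14%, 1.55 to 2.89%), so that the interval of KO replicate 1 takes in both WT values. Without KO replicate 2 the difference went from -0.839 to -0.456 percentage points. Thinning left out 28 and 78 beta-like cells with fewer UMIs in KO and 423 and 267 in WT; counted over all beta-like cells the same cycling cells were 1.46% and 0.709% in KO and 1.48% and 1.89% in WT. Without thinning the groups overlapped, at 1.91% ± 1.04 and 2.92% ± 0.948 (exact permutation p = 0.667). In alpha-like cells no thinned cell had at least 2 markers in any mouse, which at that depth allows a share of up to 0.932% to 1.44% depending on the mouse, and unthinned 1 cell each of KO replicate 2 and WT replicate 2 did. Alpha-like cells with at least 1 marker were 1.44% and 4.04% in KO and 1.07% and 0.948% in WT when thinned. Unthinned they were 5.14% and 6.65% against 2.71% and 4.63% (exact permutation p = 0.33 at each depth). Thinning rests on 1 random draw. In the draw with doublets kept, these thinned shares were 1.93% and 3.12% in KO and 0% and 0.952% in WT. The beta-like difference in cells with at least 2 markers was then -0.674 percentage points.

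**Figure D3:**
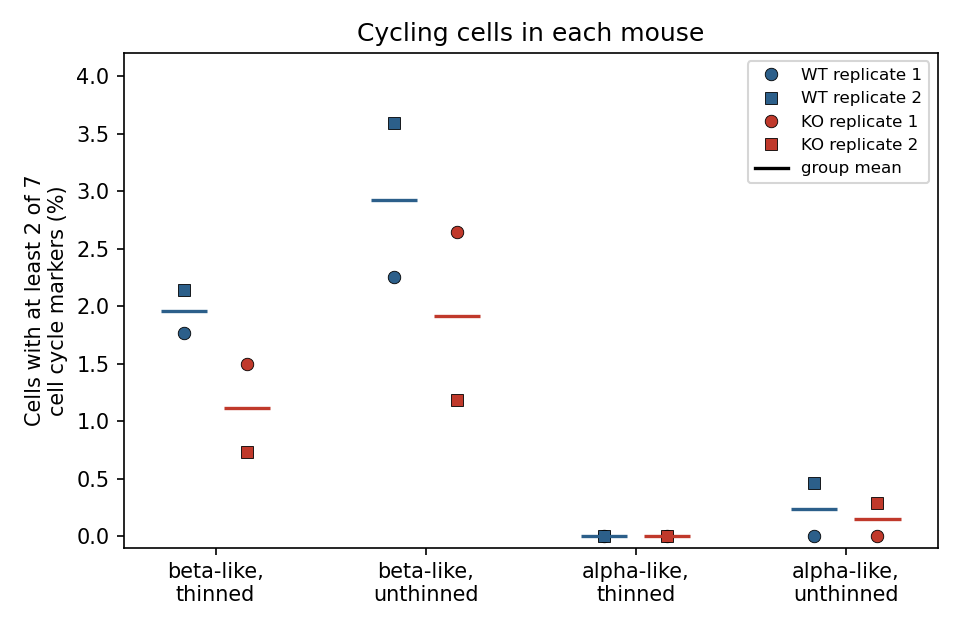
Share of beta- and alpha-like cells with at least 2 of 7 cell cycle markers (percent) in each mouse, thinned to 10000 UMIs per cell and unthinned, with WT in blue, KO in red, circles for replicate 1, squares for replicate 2 and bars for group means. Thinned beta-like shares were 1.5% and 0.731% in KO and 1.76% and 2.14% in WT; unthinned shares of the groups overlap.

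In alpha-like cells no gene passed. Higher in KO without passing were Try4 at 1.18 (adjusted p = 0.112), the fibrinogen gene Fgb at 1.0 (0.112), Fam43a at 0.65 (0.430), Ins1 at 0.58 (0.430) and the beta cell glucose-6-phosphatase gene G6pc2 at 0.79 (0.508). Lower without passing were Ifit1bl1 at -3.89 (0.430), the nuclear receptor gene Nr4a2 at -0.88 (0.562), Adgrg1 at -0.47 (0.562), Acrbp at -1.55 (0.562) and the sterol synthesis gene Msmo1 at -0.38 (0.562). Ifit1bl1 was seen at 3.03 CPM or less in each mouse. Gcg stood at 0.22 (SE 0.08, adjusted p = 0.883), with 278988 ± 15840 CPM in KO and 239872 ± 7898 CPM in WT. Cholesterol synthesis genes fell, 4 of 24 higher with a median of -0.18 (camera adjusted p = 2.7e-06); this list also passed by fry (adjusted p = 0.00750). Its adjusted p = 0.664 with an estimated correlation; none of its members passed over all genes and 1 passed adjusted over the list alone.

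Ribosomal protein genes rose in alpha-like cells, 78 of 80 higher with a median of 0.10 (camera adjusted p = 1.4e-11), and digestive enzymes rose, 17 of 21 higher with a median of 0.27 (camera adjusted p = 9.8e-11). Beta cell function genes rose, 17 of 24 higher with a median of 0.12 (camera adjusted p = 2.3e-05). For each of these 3 lists the adjusted p = 0.664 with an estimated correlation, none of their members passed over all genes, and 1, 7 and 5 members passed adjusted over the list alone. Beta cell markers made up 4.98% ± 0.374 of alpha-like UMIs in KO and 4.0% ± 0.768 in WT, and pancreatic polypeptide cell markers 11% ± 2.43 and 11.6% ± 0.0138. The enzyme list was lost without WT replicate 1 (adjusted p = 0.275) and beta cell function without WT replicate 2 (0.216). The test covered 11560 genes on 6356359 to 8581221 UMIs per mouse. By edgeR 0 genes passed and 627 had an unadjusted p under 0.05, DESeq2 called 0, and the groups did not overlap in 35.2% of genes, against 33.3% by chance. Leaving out a mouse gave 12 and 7 calls without KO replicates 1 and 2 and 82 and 20 without WT replicates 1 and 2. The strict cell filter gave 12.

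Whether alpha- and beta-like cells differ in their response was tested as an interaction, and 4 of 14757 genes passed. For Gcg and Higd1a the change in alpha-like cells lay above that in beta-like cells, by 0.996 (SE 0.11, adjusted p = 0.000184) and 1.68 (SE 0.20, adjusted p = 0.000184). The alpha-like changes were 0.22 and 0.28, neither passing, and the beta-like ones -0.78 and -1.42. For the phosphodiesterase gene Pde10a and the glucose-responsive gene Txnip the difference was -0.74 (SE 0.13, adjusted p = 0.0358) and -0.52 (SE 0.09, adjusted p = 0.0394). Without beta-like cells rich in Gcg the difference was -0.08 for Gcg and 0.51 for Higd1a (adjusted p = 1 each), -0.74 for Pde10a (0.0742) and -0.51 for Txnip (0.0855), and 0 genes passed in edgeR, with 659 at an unadjusted p under 0.05. With all cells 662 genes had an unadjusted p under 0.05 in edgeR. The count was 72 without WT replicate 1, 41 without KO replicate 2 and 16 without WT replicate 2.

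In delta-like cells inducible heat shock transcripts and beta cell transcripts were lower in KO. Hspa1a and Hspa1b, which encode inducible Hsp70 chaperones, fell by 2.37 (SE 0.24, adjusted p = 0.000201) and 2.04 (SE 0.26, adjusted p = 0.00234). Hspa1a stood at 13.4 ± 6.62 CPM in KO and 71.6 ± 20.6 CPM in WT (SD, n = 2). Their co-chaperone gene Dnajb1 fell by 0.96 (adjusted p = 0.0361) and the membrane protein gene Tm4sf1 fell by 2.28 (adjusted p = 0.00752). The beta cell genes Ucn3 and G6pc2 fell by 1.46 (adjusted p = 0.00841) and 0.79 (adjusted p = 0.0483). Beta cell markers as a whole made up 6.37% ± 1.13 of delta-like UMIs in KO and 9.80% ± 2.79 in WT, while pancreatic polypeptide cell markers were higher in KO, at 9.36% and 9.15% against 8.13% and 4.18%. The beta cell marker share was largest in WT replicate 2, at 11.8%. Alpha cell markers made up 6.92% in KO and 6.62% in WT, and delta cell markers 10.3% and 9.91%. The sums of this class are therefore not of delta cell transcripts alone. With Leiden resolution 2.0 a pancreatic polypeptide class split off, and delta-like cells were 5.11% of kept cells in KO and 4.52% in WT. Ins2 stood at -0.74 (SE 0.23, adjusted p = 0.727). The trypsinogen gene Try5 rose by 1.36 (adjusted p = 0.00752) and the phosphatase regulator gene Ppp1r17 by 0.89 (adjusted p = 0.0483). Tuba1c at 0.87, the interferon-regulated Irf1 at 0.48 and Wdyhv1 at 0.81 followed without passing (adjusted p from 0.256 to 0.411).

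The delta-like test covered 11452 genes on 3857978 to 5250371 UMIs per mouse, and edgeR called 8, while 563 had an unadjusted p under 0.05. DESeq2 called 1 gene, and the groups did not overlap in 34.5% of genes, against 33.3% by chance. By DESeq2 the adjusted p of Hspa1a was 0.127 and that of Hspa1b 1, at -2.40 and -2.09. The count was 48 without WT replicate 1, 20 without KO replicate 2 and 3 without WT replicate 2. Without WT replicate 2 the adjusted p was 0.257 for Dnajb1, 0.277 for G6pc2, 0.0609 for Ucn3, 0.380 for Ppp1r17 and 0.155 for Tm4sf1. Without KO replicate 1 it was 0.212 for Dnajb1, 0.416 for G6pc2 and 0.165 for Ppp1r17, and without KO replicate 2 the changes of Hspa1a and Hspa1b were both -3.03. With large barcodes left out G6pc2 stood at -0.13 and Ucn3 at -0.30 (adjusted p = 0.993 each), and with the authors' barcodes G6pc2 was higher in KO at 0.44 (adjusted p = 0.995). Over all alternatives the adjusted p of the 8 genes ranged from 2.5e-41 for Hspa1a to 1 for Hspa1b.

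As lists, beta cell function fell in delta-like cells, 5 of 24 higher with a median of -0.31 and 2 passing (10 adjusted over the list alone; camera adjusted p = 9.7e-16). Heat shock proteins fell, 2 of 11 higher with a median of -0.09 and 3 passing (3 adjusted over the list alone; camera adjusted p = 1.2e-10). Cholesterol synthesis fell, 5 of 24 higher with a median of -0.24 and none passing on either scale (camera adjusted p = 5.2e-07). Inflammatory genes of the NF-kappaB list rose, 9 of 10 higher with a median of 0.32, none passing over all genes and 4 adjusted over the list alone (camera adjusted p = 1.9e-05). For each of these 4 lists the adjusted p = 0.603 with an estimated correlation. Digestive enzymes rose, 17 of 20 higher with a median of 0.37, 1 passing and 5 adjusted over the list alone (camera adjusted p = 7.6e-10; adjusted p = 0.603 with an estimated correlation), but not without WT replicate 2 (adjusted p = 0.918). Camera called 15 of 30 lists, and 6 without WT replicate 2.

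Macrophage-like cells showed the same pair of Hsp70 genes lower in KO. Hspa1a fell by 5.83 (SE 0.68, adjusted p = 0.00491), from 154 and 785 CPM in WT to 6.72 and 9.29 CPM in KO, and Hspa1b by 5.59 (SE 0.75, adjusted p = 0.0123). Heat shock proteins as a list fell, 0 of 11 higher with a median of -0.79, 2 passing and 6 adjusted over the list alone (camera adjusted p = 1.1e-16). Digestive enzymes rose, 17 of 17 higher with a median of 1.22, none passing over all genes and 12 adjusted over the list alone (camera adjusted p = 9.1e-35). For both lists the adjusted p = 0.940 with an estimated correlation. Try5 at 2.11 (adjusted p = 0.126), Prss2 at 1.34 (0.608) and Anxa11 at 1.57 (0.608) were higher without passing, and the stress cytokine gene Gdf15 was lower at -2.29 (0.633). The test covered 6075 genes on 744090 to 1202976 UMIs per mouse; edgeR called 2, DESeq2 called 3, and 260 had an unadjusted p under 0.05. Both calls were lost when the sums were thinned to the smallest (adjusted p = 0.244 each, at -5.65 and -5.48), and Hspa1b also with the authors' barcodes (0.0696) and with large barcodes left out (0.0560). Without WT replicate 2 the changes were -4.23 and -3.69, and without WT replicate 1 they were -6.56 and -6.39. Over all alternatives their adjusted p ranged from 3.6e-88 to 0.244. The count of genes was 26 and 19 without KO replicates 1 and 2 and 114 and 27 without WT replicates 1 and 2.

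**Figure D4:**
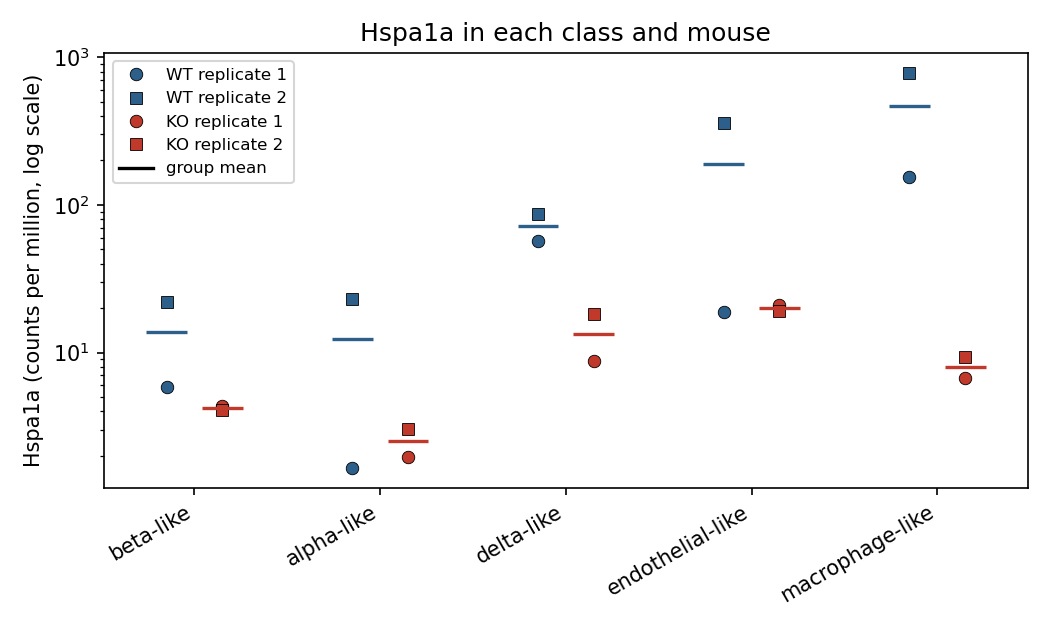
Hspa1a (CPM, log scale) in 5 classes of each mouse, with WT in blue, KO in red, circles for replicate 1, squares for replicate 2 and bars for group means. Beta-, delta- and macrophage-like cells separate the groups, beta-like cells without passing; in alpha- and endothelial-like cells WT replicate 1 lies at or below the KO mice and WT replicate 2 lies above them.

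Endothelial-like cells gave no gene past the threshold, and enzyme transcripts again lay higher in KO. Digestive enzymes rose as a list, 18 of 19 higher with a median of 0.57, none passing over all genes and 9 adjusted over the list alone (camera adjusted p = 4.4e-22; adjusted p = 0.856 with an estimated correlation). The potassium channel gene Kcnj8 at 1.47, Try5 at 1.49 and the focal adhesion gene Zyx at 0.76 were higher, and Tiparp at -0.87, Atoh8 at -1.16 and the immediate early gene Ier3 at -0.85 were lower (adjusted p = 0.996 each). Immediate early genes fell as a list, 3 of 17 higher with a median of -0.23, none passing over all genes and 1 adjusted over the list alone (camera adjusted p = 6.9e-05; adjusted p = 0.856 with an estimated correlation), but not without WT replicate 2 (adjusted p = 0.747). By edgeR 0 of 8680 genes passed on 1649345 to 2194612 UMIs per mouse, 354 had an unadjusted p under 0.05, and DESeq2 called 1. Leaving out a mouse gave 2 and 26 calls without KO replicates 1 and 2 and 112 and 39 without WT replicates 1 and 2.

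For exocrine function, acinar-like cells were few: 8 and 4 in KO and 6 and 13 in WT. They were 0.230% ± 0.190 of kept cells in KO and 0.273% ± 0.179 in WT (exact permutation p = 0.667). The share was 0.364% (exact 95% interval 0.157 to 0.717%) and 0.0955% (0.0260 to 0.244%) in KO and 0.146% (0.0536 to 0.318%) and 0.399% (0.213 to 0.682%) in WT. On 84821 to 274609 UMIs per mouse, 347 genes could be tested; edgeR called 0 with 12 at an unadjusted p under 0.05, and DESeq2 called 0. The ribosomal protein genes Rpl23a at 1.38 and Rpl5 at 0.68, with Ndufv3 at 1.85 and Lars2 at 1.13, were higher without passing (adjusted p = 0.927 each). Ubb at -1.74, Rbm39 at -2.81, Vmp1 at -2.98, Ins2 at -1.30 and Ins1 at -1.45 were lower without passing (adjusted p = 0.927 each). Ribosomal proteins rose as a list, 56 of 78 higher with a median of 0.29 (camera adjusted p = 1.2e-07), and mitochondrially encoded genes fell, 0 of 10 higher with a median of -0.90 (camera adjusted p = 8.6e-07). For both, the adjusted p = 0.544 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. The mitochondrial list was lost without WT replicate 1 (adjusted p = 0.494) and without KO replicate 2 (0.801). Leaving out WT replicate 1 gave 54 genes and leaving out KO replicate 2 gave 2. The interaction with beta-like cells passed for 1 gene, the nuclear noncoding RNA gene Malat1, at -3.07 (SE 0.60, adjusted p = 0.00425), fitted on both classes together. The groups overlap in acinar-like cells, at 1371 and 150 CPM in KO and 1356 and 23210 CPM in WT. The count was 2 without WT replicate 1, 0 without KO replicate 2 and 0 without WT replicate 2, with 21 and 45 genes at an unadjusted p under 0.05 in edgeR. When the clustering was coarser, a further cluster of low-UMI cells with enzyme transcripts joined the class, and the difference in share became 6.12 percentage points (exact permutation p = 0.33). With the strict cell filter it was 2.16 points, at 3.11% and 3.42% in KO and 0.849% and 1.35% in WT. The clusters named acinar-like with the coarser clustering and with the strict filter were rich in insulin. Ins2 stood at 3205.2 and 4004.5 and Prss2 at 250.1 and 52.9 per 10000 UMIs. The main acinar-like cluster had 82.1 and 949.6, so these wider shares are not of acinar cells alone.

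The deleted gene itself could not be followed. Mir216a (ENSMUSG00000065539, GRCm38 chromosome 11, 28757012 to 28757083, plus strand) is not among the genes counted. It lies in the intron from 28754147 to 28770484 of the noncoding host gene Mir217hg (ENSMUSG00000085510, 28751633 to 28815767). Mir217hg gave 1 and 4 UMIs in KO (0.00739 and 0.0203 CPM) and 0 and 0 in WT. A count of 0 allows up to 0.0157 and 0.0162 CPM there. KO replicate 1 lies below these limits and KO replicate 2 above them, so these few UMIs do not settle whether the groups differ. Within 2 Mb of Mir216a 0 of 17 tested genes passed in beta-like cells by edgeR, 2 of them with an unadjusted p under 0.05. Of the literature targets, these did not pass in beta-like cells: the TGF-beta inhibitor Smad7 stood at 0.17 (SE 0.10), Ybx1 at 0.04 (SE 0.06), Becn1 at 0.05 (SE 0.06) and Jak2 at 0.01 (SE 0.08), with adjusted p from 0.775 to 0.986.

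Loss of a microRNA could be read in genes that carry its seed site in the 3' untranslated region. In beta-like cells the median of 1731 such genes lay -0.018 from that of genes without a site, at percentile 72.5 of 858 matched sequences. Most matched sequences gave differences from -0.029 to -0.013, so the background was itself negative. A negative difference alone therefore does not show that genes with the seed site fell. In alpha-like cells the difference was -0.036 for 1518 genes at percentile 82.8 of 849, and in acinar-like cells -0.244 for 18 genes at percentile 24.2 of 768. Most matched sequences lay from -0.052 to -0.030 in alpha-like and from -0.525 to 0.144 in acinar-like cells. For 8-base sites alone the percentile was 96.7 in beta-like, 98.9 in alpha-like and 74.5 in acinar-like cells. The alpha-like difference for these sites was -0.020, above most matched sequences (-0.065 to -0.024). The beta-like one was -0.010, within the range of most matched sequences (-0.036 to -0.0093). For genes of at least 50 CPM the percentile was 92.6 in beta-like and 39.5 in alpha-like cells. The beta-like percentile was 6.64 without KO replicate 1 and 9.95 without WT replicate 2, the alpha-like one 16.5 without WT replicate 1 and the acinar-like one 43.8 without WT replicate 2. Smad7, Ybx1 and Jak2 carry 1 such site and Becn1 none.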

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

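The tests of explanations below were chosen after the values they bear on had been seen, and so were the repeats of the interaction. Leaving out beta-like cells rich in Gcg (over 0.5% of UMIs) was also chosen after the data were seen, though before its own result was. The test of a genotype effect on Gcg replaced an earlier one on Ppy, whose change in beta-like cells (-0.57, adjusted p = 0.680) decided nothing.

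For 5 genes the change with genotype differed between 2 classes of the same mice in a test of the difference itself, and in each of them the fitted changes of the 2 classes have opposite signs. Gcg stood at 0.22 in alpha-like and -0.78 in beta-like cells, a difference of 0.996 (SE 0.11, adjusted p = 0.000184); without beta-like cells rich in Gcg the beta-like value was 0.26 and the difference -0.08 (SE 0.23, adjusted p = 1). Higd1a stood at 0.28 in alpha-like and -1.42 in beta-like cells, a difference of 1.68 (SE 0.20, adjusted p = 0.000184), at 140 to 185 CPM in alpha-like and 0.293 to 1.08 CPM in beta-like cells. Pde10a stood at -0.68 and 0.09, a difference of -0.74 (SE 0.13, adjusted p = 0.0358), and Txnip at -0.29 and 0.24, a difference of -0.52 (SE 0.09, adjusted p = 0.0394). Without the same cells Higd1a stood at -0.27 in beta-like cells (adjusted p = 0.917), and the differences of Higd1a, Pde10a and Txnip were 0.51 (SE 0.32, adjusted p = 1), -0.74 (SE 0.13, 0.0742) and -0.51 (SE 0.09, 0.0855), so that none of the 4 genes passed; in edgeR 659 genes had an unadjusted p under 0.05. Malat1 stood at -4.0 in acinar-like and 0.21 in beta-like cells, and the difference fitted on both classes together, rather than taken from these 2 separate fits, was -3.07 (SE 0.60, adjusted p = 0.00425). The count of such genes between acinar- and beta-like cells was 0 without KO replicate 2 and 0 without WT replicate 2 in edgeR, with 21 and 45 genes at an unadjusted p under 0.05. On simulated counts 10.3% of the calls between alpha- and beta-like cells and 2.26% of those between acinar- and beta-like cells were false, but on the 11468 and 338 genes tested in both classes, where the tests above covered 14757 and 13417.

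Digestive enzyme transcripts were higher in KO as a list in each of the 5 larger classes, though not without WT replicate 1 in alpha-like (adjusted p = 0.275) and without WT replicate 2 in delta-like cells (0.918), and with an estimated correlation the adjusted p = 0.497 to 0.940 over these classes. Free RNA from acinar cells stays open as a candidate source: mean enzyme UMIs per cell differed 1.48-fold over the 5 classes while total UMIs per cell differed 5.59-fold, and Ctrb1 and Prss2 stood at 139996 and 92841.5 CPM in acinar-like and 58.4 and 45.9 CPM in beta-like cells of KO mice. More intact acinar cells in the KO suspensions cannot be told apart from it. The share of acinar-like cells differed by -0.0427 percentage points, with overlapping groups of 4 to 13 cells per mouse. With the strict filter it differed by 2.16 points and with the coarser clustering by 6.12 points, both KO mice above both WT mice. The clusters so named there were rich in insulin, with Ins2 at 4004.5 and 3205.2 and Prss2 at 52.9 and 250.1 per 10000 UMIs. The main acinar-like cluster had 82.1 and 949.6, so these wider shares cannot tell the number of intact acinar cells. Higher enzyme expression in KO beta-like cells cannot be told apart from free RNA either, since other classes go both ways. The change in beta-like cells lay by a median of -0.19 from that in macrophage-like cells. It lay by 0.28, 0.64 and 0.65 from that in endothelial-, alpha- and delta-like cells. Why KO suspensions would hold more enzyme RNA, through genotype, dissection or handling, was not tested, and 14 of the 33 enzymes listed are also among the fixed acinar markers.

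Lower Gcg in beta-like cells of KO mice went with fewer cells rich in it: Gcg took over 0.5% of UMIs in 0.547% and 0.748% of KO and 4.19% and 1.03% of WT beta-like cells. Without the cells rich in Gcg the change was 0.26 (adjusted p = 0.812; 6.2e-29 to 0.812 over all alternatives), so doublets of beta and alpha cells, fewer in KO, may account for it. Gcg, Ppy and Pyy, at 239872, 70220.7 and 41751.3 CPM in WT alpha-like cells, stood at -0.78, -0.57 and -0.40 in beta-like cells, the latter 2 without passing (adjusted p = 0.680 and 0.741). Less free RNA from alpha cells and a genotype effect on the typical beta-like cell cannot be told apart from this: the groups overlap in the median Gcg UMIs of endothelial-like cells (3 and 2 in KO, 2 and 1 in WT, log2 ratio 0.74) and of beta-like cells (12 and 9, 9 and 7, 0.39), neither corrected for total UMIs. The limit selects on Gcg itself, so cells that express both hormones stay open beside doublets; WT replicate 1 had the largest share of such cells, and without it the change was -0.68 (adjusted p = 0.0221).

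The G2 and M phase list was lower in beta-like cells of KO mice, with 0 of 28 genes higher and a median of -0.76. WT replicate 2 alone is argued against by a camera adjusted p of 8.3e-31 without it. A difference in UMIs per cell cannot be told apart from a genotype effect: with 10000 UMIs in every cell the share of cycling cells differed by -0.839 percentage points, but thinning left out 28 and 78 KO and 423 and 267 WT cells, and unthinned KO replicate 1 (2.65%) lay above WT replicate 1 (2.25%), as did its share in the cell cycle cluster (2.01% against 1.94%). A genotype effect on proliferation and a difference between single mice cannot be told apart. The list's genes move together within a mouse, and there are 2 mice per group. By camera with an estimated correlation the list had an adjusted p = 0.577, but the power of that test here was not simulated, so it decides nothing. KO replicate 2 had the lowest share and without it the difference in cycling cells was -0.456 points, while the exact 95% interval of KO replicate 1 (0.859 to 2.42%) takes in both WT values of 1.76% and 2.14%.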

How the results depend on the processing

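Chosen after the data were seen were the authors' barcodes, the UMI ceiling, leaving out clusters mostly of 1 mouse, leaving out cells rich in Gcg, counting unnamed clusters as beta-like, the coarser clustering for the acinar-like gene test, and leaving out each mouse or the cells rich in Gcg in the interaction, and each mouse in the cycling and seed tests. Of the values of the main answers under alternatives, 148 were kept and 78 moved. A value was kept if it moved by less than the spread between mice or stayed within 1.5 times a count. For seed sites the limit was the SD of the percentiles with each mouse left out, so those values helped to set their own limit. For single named genes 661 values kept their side of the threshold and their direction if called. Another 81 newly passed, 43 no longer passed and 2 reversed. The kept values include genes that passed in neither setting, and alternatives that change few cells or genes. All 53 values were kept with doublets kept and with sex-linked genes left out. For lists 244 values were kept, 171 no longer passed and 10 reversed. Where no cause is named, the cause was not tested. Depth limits the smaller classes: simulated changes of 1 log2 unit were found in 84% of genes in beta-like, 37% in macrophage-like and 10% in acinar-like cells.

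The mean share of beta-like cells was lower in KO under each alternative tried, from -15.6 to -4.10 percentage points, and those of delta- and macrophage-like cells higher, from 0.502 to 1.84 and from 0.762 to 1.12 points. With the authors' barcodes the groups overlapped in all 3 (exact permutation p = 1, 0.667 and 0.667), with 59.9% beta-like cells in WT replicate 2 against 67.2% and 61.1% in KO. The -4.10 points come from counting the low-UMI enzyme-bearing cluster as beta-like, where the groups overlap too (exact permutation p = 0.667); with all 5 unnamed clusters closest to beta cells it is -4.64 points without overlap. Unnamed cells, more frequent in KO by 5.80 points, differed by -0.596 points with the strict filter and -1.22 points with Leiden resolution 0.5. Without any filter on low counts edgeR called 302 genes in beta-like cells (6 as reported), 56 in alpha-like (0), 45 in delta-like (8), 3 in acinar-like (0) and 113 in endothelial- and macrophage-like cells together (2), and 51 in the interaction of alpha- and beta-like cells (4). With DESeq2 the counts were 46 in beta-like, 1 in delta-like and 4 in the last 2 classes together. The strict cell filter gave 2 in beta-like, 12 in alpha-like and 13 in acinar-like cells. Under that filter the difference in acinar-like share went from -0.0427 to 2.16 points, and with Leiden resolution 0.5 to 6.12 points. The cluster so named holds 249 cells with a median of 34722 UMIs under the filter. With Leiden resolution 0.5 low-UMI cells join it (438 cells, median 2877.5 UMIs). Both clusters were rich in insulin, with Ins2 at 4004.5 and 3205.2 and Prss2 at 52.9 and 250.1 per 10000 UMIs. The main acinar-like cluster had 82.1 and 949.6, so the strict-filter calls and these shares are not of acinar cells alone. With the authors' barcodes the count was 0 in beta-like cells (edgeR, 780 genes at an unadjusted p under 0.05, DESeq2 not run there). It was 2 in endothelial-like and 1 in macrophage-like cells, and 2 in a pancreatic polypeptide class tested under these barcodes alone. The share differences were 1.24 points in alpha-like and -0.985 points in acinar-like cells. Among endocrine cells alone, whose smaller total raises each share, the differences were 4.01 points for alpha-like and 1.84 for delta-like cells.

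The UMI ceiling gave 3 genes in beta-like cells, 1 in alpha-like and 1 in endothelial- and macrophage-like cells together. Thinning to the smallest sum left 0 in these 2 classes (edgeR, with 378 and 226 genes at an unadjusted p under 0.05). Leaving out clusters mostly of 1 mouse gave 12 in beta-like cells. Leaving out genes of other classes gave 0 in beta-like cells (edgeR, 1006 at an unadjusted p under 0.05), since the 6 called genes are themselves markers or enzymes of other classes, and 5 in delta-like cells. With at least 1 cycling marker the difference in cycling cells was -1.34 points. Seed site percentiles were 39.5 in alpha-like cells for genes of at least 50 CPM and 74.5 in acinar-like cells for 8-base sites alone, where 6 genes remain; those sites alone gave 96.7 in beta-like and 98.9 in alpha-like cells, and genes of at least 50 CPM 92.6 in beta-like cells. Without beta-like cells rich in Gcg the interaction of alpha- and beta-like cells gave 0 genes (edgeR, 659 at an unadjusted p under 0.05).

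With an estimated correlation 0 lists were called in each of beta-, alpha-, delta-, acinar-, endothelial- and macrophage-like cells. That test has few degrees of freedom with 2 mice per group and its power was not simulated, so this says little about the lists. Fry called 1 in alpha-like cells and 0 in each of the other 5 classes. Gcg in beta-like cells reversed to 0.26 without cells rich in it, and G6pc2 in delta-like cells to 0.44 with the authors' barcodes.

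Leaving out each mouse in turn leaves a lone mouse in 1 group, assumed to vary like the other group. It gave 6 to 118 genes in beta-like, 7 to 82 in alpha-like, 3 to 48 in delta-like, 0 to 54 in acinar-like (347 tested, 12 at an unadjusted p under 0.05 with all mice) and 28 to 226 in endothelial- and macrophage-like cells together. The count of lists was 5 to 14 in alpha-like (9 with all mice), 6 to 18 in delta-like (15), 2 to 5 in acinar-like (3), 7 to 14 in endothelial-like (5) and 5 to 8 in macrophage-like cells (9). The interaction with beta-like cells gave 4 to 72 genes for alpha-like and 0 to 2 for acinar-like cells. Seed site percentiles were 6.64 to 76.3 in beta-like, 16.5 to 90.6 in alpha-like and 18.4 to 43.8 in acinar-like cells. Lists that reversed without a mouse had adjusted p values, from lowest to highest over the left-out mice, of 7.9e-22 to 0.881 for interferon response in beta-like cells and 6.3e-05 to 0.983 for beta cell function in acinar-like cells. In endothelial-like cells these were 5.5e-10 to 0.591 for glycolysis, 2.9e-06 to 0.850 for hypoxia response and 2.0e-20 to 0.764 for heat shock proteins. In macrophage-like cells they were 2.9e-33 to 0.383 for alpha cell function, 1.4e-16 to 0.423 for secretory granules and 0.000258 to 0.994 for ribosomal proteins.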

Other observations

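The test of cluster-level expression in low-UMI cells was chosen after the data were seen; the lists were fixed before. A cluster of 407 low-UMI cells, left unnamed and scoring closest to beta cells, came mostly from KO mice. It held 204 and 167 KO cells and 25 and 11 WT cells, 6.64% ± 3.75 of kept cells in KO and 0.473% ± 0.192 in WT (SD, n = 2; exact permutation p = 0.33). Its median was 2827 UMIs, its leading genes were Reg2 and Try4, and 50.3% to 62.4% of its UMIs were of beta cell markers and 3.54% to 9.75% of digestive enzymes. Between genotypes 5 of 3533 genes passed in edgeR, and 480 had an unadjusted p under 0.05. Fosb fell by 2.07, Ttc32 fell by 2.72 and Bdp1 fell by 2.62, while Ppy and Sst rose by 2.49 and 4.59 (adjusted p from 0.0378 to 0.0455); these genes were chosen after their values were seen, and WT replicate 2 gave fewer cells than the minimum of 20.

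Among beta-like cells, a cluster led by Mafa, Slc2a2 and Ucn3, genes of mature beta cells, made up 24.7% of WT replicate 2 and 6.75%, 3.78% and 7.18% of KO replicates 1 and 2 and WT replicate 1. The cluster led by cell cycle genes made up 2.01% and 0.906% of beta-like cells in KO and 1.94% and 2.65% in WT (exact permutation p = 0.667). Few acinar-like cells were found, but those of KO mice were larger in UMIs, at 34326.1 and 35721.2 per cell against 14136.8 and 11863.5 in WT. Hspa1a, which passed in delta- and macrophage-like cells, stood at -1.73 in beta-like (adjusted p = 0.660), -2.23 in alpha-like and -3.20 in endothelial-like cells (adjusted p = 0.996), without passing in these. Gcg in WT replicate 1 stood at 6220 CPM in macrophage-like and 3025 CPM in endothelial-like cells, against 338 CPM or less in the other mice.

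Further lists moved in beta-like cells. Hypoxia response genes fell, 3 of 11 higher with a median of -0.10 (camera adjusted p = 0.000456; 2 adjusted over the list alone; adjusted p = 0.510 with an estimated correlation). Interferon response genes fell, 4 of 25 higher with a median of -0.17 (camera adjusted p = 0.000381; adjusted p = 0.702 with an estimated correlation), but pointed up without KO replicate 1 (0.449) and without WT replicate 2 (0.881). Extracellular matrix genes fell, 0 of 6 higher with a median of -0.18 (0.0411), though not without KO replicate 2 (0.944) and WT replicate 1 (0.0899). Acinar identity regulators rose, 6 of 7 higher with a median of 0.09 (0.0446; 1 adjusted over the list alone), though not without KO replicate 2 (0.647), WT replicate 1 (0.106) and WT replicate 2 (0.0549). For these 2 lists the adjusted p = 0.695 and 0.599 with an estimated correlation, and no member of the 4 lists passed over all genes.

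In alpha-like cells oxidative phosphorylation genes encoded in the nucleus rose, 68 of 76 higher with a median of 0.07 (camera adjusted p = 1.0e-04), and mitochondrially encoded genes fell, 3 of 13 higher with a median of -0.18 (4.1e-05; 2 adjusted over the list alone). Alpha cell function genes rose, 11 of 15 higher with a median of 0.14 (0.00979). Genes of PI3K and AKT signalling fell, 5 of 23 higher with a median of -0.14 (0.0117), and so did fatty acid synthesis, 2 of 10 higher with a median of -0.19 (0.0145; 1 adjusted over the list alone). With an estimated correlation these 5 lists had an adjusted p = 0.664 to 0.821, and no member passed over all genes. Without WT replicate 2 the adjusted p was 0.0834, 0.0834, 0.15, 0.651 and 0.113 in that order. Without KO replicate 1 it was 0.175 for mitochondrially encoded and 0.0668 for alpha cell function genes, and without KO replicate 2 it was 0.0559 for both PI3K and fatty acid synthesis genes.

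In delta-like cells 10 further lists passed by camera. Ribosomal proteins (78 of 80 higher, median 0.10, camera adjusted p = 1.2e-09), oxidative phosphorylation (60 of 76, 0.08, 0.000582), acinar injury (8 of 10, 0.20, 0.00486), immediate early (9 of 17, 0.05, 0.0143) and antioxidant genes (7 of 10, 0.12, 0.0400) rose. Mitochondrially encoded genes (3 of 13, -0.20, 6.0e-05), the unfolded protein response (5 of 21, -0.13, 0.000609), hypoxia response (2 of 10, -0.21, 0.0123), integrated stress response (3 of 18, -0.18, 0.0129) and fatty acid synthesis (1 of 10, -0.16, 0.0336) fell. With an estimated correlation these lists had an adjusted p = 0.603 to 0.750; no member passed over all genes, and 4 immediate early, 1 mitochondrially encoded and 1 hypoxia gene passed adjusted over the list alone. Without WT replicate 2 the adjusted p was 0.0589 for ribosomal proteins, 0.984 for oxidative phosphorylation, 0.918 for acinar injury, 0.957 for immediate early, 0.180 for antioxidant, 0.297 for unfolded protein, 0.912 for hypoxia, 0.794 for integrated stress and 0.918 for fatty acid genes. Without KO replicate 2 it was 0.367 for acinar injury, 0.488 for immediate early, 0.712 for antioxidant, 0.0554 for hypoxia and 0.379 for fatty acid genes. Without KO replicate 1 it was 0.217 for unfolded protein and 0.0644 for integrated stress genes, and without WT replicate 1 it was 0.140 for antioxidant and 0.0611 for mitochondrially encoded genes.

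In macrophage-like cells inflammatory genes of the NF-kappaB list rose, 17 of 18 higher with a median of 0.22 (camera adjusted p = 0.00238), and interferon response genes rose, 21 of 26 higher with a median of 0.18 (0.0125). TGF-beta and SMAD genes (4 of 18, -0.28, 0.0102; 1 adjusted over the list alone), mitochondrially encoded genes (2 of 13, -0.24, 0.00899) and ribosomal proteins (7 of 80, -0.08, 0.0485) fell. Genes of endocrine cells fell too, those of alpha cell function (1 of 5, -1.20, 0.0248; 3 adjusted over the list alone) and of secretory granules (0 of 10, -0.55, 0.00632). For each of the 7 lists the adjusted p = 0.940 with an estimated correlation, and no member passed over all genes. Without WT replicate 1 the endocrine lists pointed up (0.383 and 0.423), as did ribosomal proteins (0.994), and mitochondrially encoded genes were at 0.769. Without KO replicate 1 the adjusted p was 0.356 for NF-kappaB, 0.0716 for mitochondrially encoded and 0.0516 for granule genes. Without KO replicate 2 it was 0.999 for interferon, 0.0988 for TGF-beta, 0.155 for mitochondrially encoded and 0.830 for ribosomal genes, which pointed up, and without WT replicate 2 it was 0.130 for interferon and 0.501 for TGF-beta genes.

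In endothelial-like cells glycolysis (3 of 14 higher, median -0.28, camera adjusted p = 0.0114), hypoxia response (4 of 11, -0.36, 0.0328) and heat shock genes (3 of 11, -0.16, 0.0328) fell, with an adjusted p = 0.856 with an estimated correlation and no member passing over all genes or adjusted over the list alone. Without WT replicate 2 all 3 pointed up (0.591, 0.635 and 0.764), and without KO replicate 2 they were at 0.261, 0.850 and 0.158. In acinar-like cells beta cell function genes fell, 0 of 5 higher with a median of -0.62 (0.00255; adjusted p = 0.544 with an estimated correlation, none passing on either scale). That list was at 0.402 without KO replicate 2 and pointed up without WT replicate 1 (0.983).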
